A study of Homo sapiens with 4 samples.

How the data were processed

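RNA sequencing libraries were made from PC-3 cells transfected with control siRNA (2 libraries) or with siRNA against WHSC1 (2 libraries), with RNA taken after 72 h. Per the labels' protocols, the cells were grown in RPMI medium with fetal bovine serum, RNA was extracted with Trizol and cleaned on RNeasy columns, and the libraries were sequenced on a HiSeq instrument. Samples were grouped by the sample titles. The titles number the libraries of each group 1 and 2, and no label says that the numbers mark a shared culture or day. The submitters' design text speaks of 2 independent siRNAs tested in duplicate. Since only 2 siWHSC1 libraries were at hand and no siRNA sequence was given, both were taken as 1 group.

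Per the labels' protocols, the authors mapped the reads to hg19 with BWA and Bowtie (Bowtie2 per the submitters' processing notes) and quantified gene expression levels with RSEM. The versions of these tools, the gene annotation release, the read length, the strand setting and any read filter were not given in the sources used here. The deposited expected counts are RSEM estimates per gene, in which reads that map to several genes are divided between them, per the labels' protocols and the file headers. They were not normalized. Between 65.7% and 66.1% of the values per library were whole numbers within a tolerance of 1e-09. The deposited FPKM values (fragments per kilobase of gene length, scaled to the library's total) were made by the authors with RSEM and stand beside the counts, per the labels' protocols and the file headers. The same tables hold a gene length, which RSEM computes as a mean over a gene's isoforms weighted by their abundance. Each library had its own table, with no pooling, and genes not listed in a library were taken as 0. A table of the whole series held the same 19781 genes and was used only for its GO and KEGG annotation. Its control columns carry a group name and a number, but these numbers were not taken to identify the control libraries. Its FPKM values were not used.

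The gene identifiers are Entrez numbers, apart from 8 RefSeq accessions. Symbols came from the NCBI RefSeq gene table for GRCh38.p14, used for names only, which matched 19686 of 19781 genes (99.5%). Coordinates are on hg19, from the GENCODE annotation mapped to GRCh37, which is the same assembly, and were found for 18617 genes. Transcript GC content was the median over a gene's annotated transcripts. Without a stated strand, reads of overlapping genes cannot be told apart. The named genes that overlap another tested gene are CORO7-PAM16, C3, TMX2-CTNND1, SENP3-EIF4A1, BIVM-ERCC5, CYP39A1, PMEPA1, MCL1, CCND1, RAD54L, FANCD2, MCM7, KRT7, CA9, KDM2B, EEF1A1, PGK1, MX1, IFIT3, LOXL2, HMMR, SOD2, PTX3, TP53INP1, PLAU, TGFB2, INHBA, CRIM1, RICTOR, ZEB1, FTH1, RPS28, LONP1 and FOXM1.

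The expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. The default filter on low counts (filterByExpr) removed 5770 genes and left 14011, TMM factors were computed, dispersions were estimated, and the quasi-likelihood test (glmQLFit with the legacy setting off, then glmQLFTest) compared siWHSC1 with control, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 3.46%, and 5024 genes had an unadjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. FPKM values are given as mean ± SD. A ratio to a group at 0 used a floor of 3 counts over the group. The total expected counts per library were 5418049 to 5516336, so that counting error limits genes with few counts, and intervals and floors cover counting error only, since the reads carry no molecular identifiers. Libraries of a group were compared by the chi-square per gene over genes with whole counts in all libraries and at least 20 counts in the pair, with 1000 bootstrap draws for the 95% interval.

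Gene lists were tested with limma 3.58.1 (camera, preset correlation of 0.01, trended variance) on log2 CPM with a prior count of 2. They were tested again with an estimated correlation and with fry. With an estimated correlation camera tests on the residual degrees of freedom, of which 4 libraries leave few. A list or term lost in that run is therefore not shown to owe its preset result to correlation between its genes. There were 27 lists, and 1 of them, some single genes and some annotation terms are not reported here. The others were H3K36 and H3K27 methylation enzymes, AKT and mTOR components, mesenchymal genes, epithelial junction and keratin genes, proteolysis and invasion, integrins and focal adhesion, DNA replication and G1/S, mitosis, CDK inhibitors and G1 cyclins, DNA repair, NF-kB targets, interferon-stimulated genes, the unfolded protein response and ATF4, cholesterol and fatty acid synthesis, glycolysis and hypoxia, WNT and Hippo targets, TGF-beta and BMP targets, apoptosis, p53 targets, androgen-responsive and luminal genes, neuroendocrine, fibroblast and blood cell markers, mitochondrially encoded genes, ribosomal proteins and housekeeping genes. Of the 27 lists, 24 had at least 3 tested members. All camera p values were adjusted over these 24, the unreported list included. Some genes stand in more than 1 list. GO and KEGG terms with 15 to 300 tested members were tested by camera as a family of their own.

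The named genes were WHSC1, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 FPKM in a group and no overlap between the groups' libraries, and up to 4 members of each list with the lowest p, 122 genes in all. Genes outside this rule are said to be named after their values were seen. The groups, tests, lists, the rule for named genes and the first set of other settings were fixed before the data were examined. These settings were RLE size factors, library size only, no filter, at least 50 counts in 2 libraries, DESeq2 1.42.0, the robust and the legacy edgeR fits, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 2 libraries, the former also without a filter, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, and each library left out in turn. In the last case the lone library was assumed to vary like the other group. A correction for GC content and the summing of readthrough genes and near-identical copies were added after seeing the data. Isoform use was tested with limma on the log2 deposited gene length.

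The scripts were tested on simulated data, in which counts for 14011 genes were drawn and 200 genes were changed. The means and library sizes were those of the 4 libraries, and the dispersion was the trend that edgeR fitted to them. The false calls are therefore those under edgeR's own model. After the filter on low counts, 13811 genes entered the test. Of the changed genes that entered the test, edgeR recovered 27.1% at 1.25-fold, 59.2% at 1.5-fold, 92.0% at 2-fold and 98.0% at 4-fold, and 4.20% of its calls were false. With no change simulated, 0 genes were called. Of 100 genes changed by 2-fold or 4-fold, edgeR recovered 95, DESeq2 80 and limma on FPKM 84. Of simulated gene sets, camera called 5 of 5 that were moved and 0 of 95 that were not. These sets were random genes simulated independently of each other, so the check does not cover correlation between the genes of a list. Every member of a moved set was shifted alike, by more than the median of any list that passed. The check therefore does not give the power for smaller shifts. The length test found 200 of 200 simulated shifts, with 12 false calls among the unshifted genes. All simulated lengths had the same noise, and the shift was far larger than it. The check therefore does not give the power for smaller shifts or for genes whose length varies more. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15 and pandas 2.3.3.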

Results

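Gene expression was measured by RNA sequencing in PC-3 cells, an androgen-independent human prostate cancer line established from a bone metastasis. The cells were transfected with a control siRNA or with siRNA against WHSC1, and total RNA was taken 72 h later. WHSC1, whose current symbol is NSD2, encodes a histone methyltransferase that dimethylates lysine 36 of histone H3. The comparison asked which transcripts differ when this enzyme is depleted. There were 2 control libraries and 2 siWHSC1 libraries. The submitters describe 2 independent siRNAs and testing in duplicate, and the labels number the siWHSC1 libraries 1 and 2, so these may carry different siRNAs or be duplicates of one. They were treated as 1 group, in which a called gene had to stand out over the spread between both. Nothing says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

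The summed expected counts were 5418049 and 5451557 in the control libraries and 5465117 and 5516336 in the siWHSC1 libraries. Between 17727 and 17903 genes were listed per library, and 13509 to 13659 of them had at least 1 FPKM. The 10 most abundant genes took 4.05% and 4.07% of the counts in the controls and 3.68% and 3.72% in the siWHSC1 libraries. Over genes with whole counts and at least 20 counts in a pair, the chi-square per gene was 1.53 between the control libraries (95% bootstrap interval 1.47 to 1.61, 8556 genes). It was 1.38 between the siWHSC1 libraries (1.34 to 1.42, 8472 genes) and 11.2 to 12.1 between libraries of different groups. Both pairs differed by more than sampling noise, for which the value is 1, and each library was counted as 1 replicate.

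The transcript of the targeted gene was lower in both siWHSC1 libraries. WHSC1 (NSD2, Entrez 7468, hg19 chromosome 4, 1873120 to 1983934, plus strand) had 34.82 and 34.13 FPKM in the control libraries and 13.45 and 11.87 FPKM in the siWHSC1 libraries. The means were 34.5 ± 0.488 and 12.7 ± 1.12 FPKM (SD, n = 2 each), which left 36.7% of the control level, a reduction of 63.3%. The expected counts behind these values were 1425 and 1409 against 556 and 497. The log2 fold change was -1.42 with a standard error of 0.06 (2.67-fold lower, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.27e-11). No other tested gene overlapped WHSC1 in the annotation.

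Depletion of WHSC1 was accompanied by many changes, most of them small. Of 14011 genes tested, 3510 (25.1%) differed between the groups, 1791 higher and 1719 lower in siWHSC1. A change of at least 2-fold was found for 349 of them, 129 higher and 220 lower, and 2467 (70.3%) changed by less than 1.5-fold. The median fold change among the called genes was 1.35. The 2 siWHSC1 values lay outside both control values for 3499 of the called genes (99.7%), against 61.4% of all tested genes and 33.3% by chance for 2 against 2 libraries. The number of calls depended on the tool and on the number of libraries, with 1417 genes called by DESeq2 and 1208 by edgeR without a filter on low counts. Without control replicate 1 or 2 the counts were 556 and 284, and without siWHSC1 replicate 1 or 2 they were 2219 and 1708. Of 158 genes that passed and were picked for single mention, by the fixed rule or after their values were seen, 87 of 157 tested kept their calls without control replicate 1. The calls of 62 were kept without control replicate 2, and those of 139 and 131 without siWHSC1 replicate 1 or 2.

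**Figure D1:**
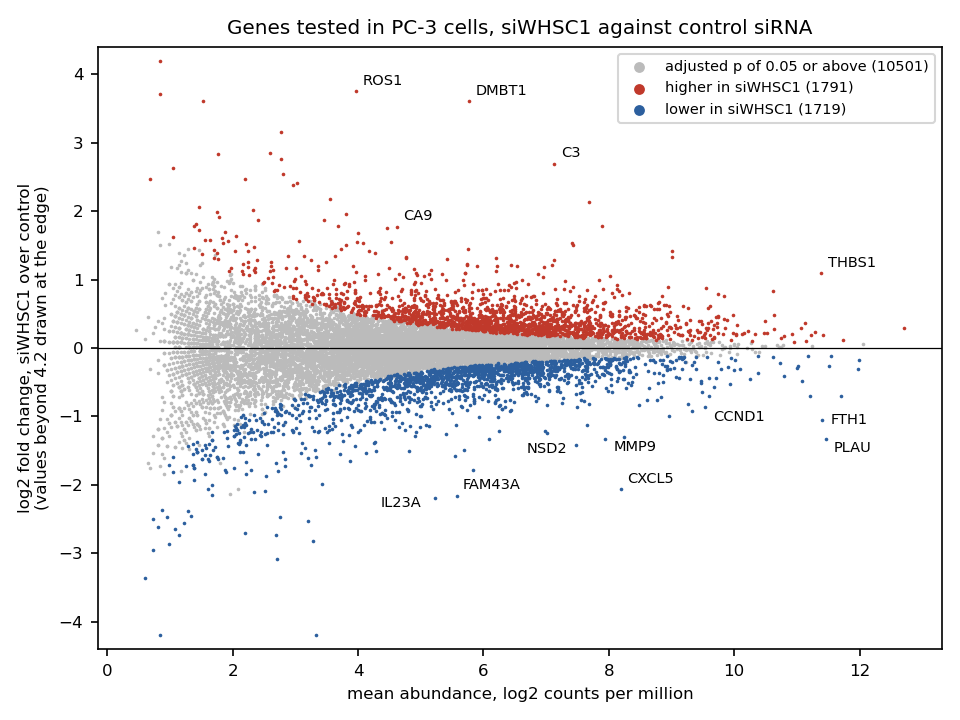
Log2 fold change of each tested gene (siWHSC1 over control, vertical axis) against its mean abundance in log2 CPM, counts scaled to library size (horizontal axis). Red points are the 1791 genes higher and blue points the 1719 genes lower in siWHSC1 at an edgeR adjusted p under 0.05, grey points are all others, and PLAU, CXCL5, DMBT1 and C3 stand apart from genes of similar abundance.

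Among abundant transcripts, the lowest p belonged to PLAU, the gene of urokinase-type plasminogen activator. It fell from 1685 ± 28.7 to 656 ± 18.4 FPKM (n = 2 each here and below, log2 fold change -1.33, SE 0.03, edgeR adjusted p = 7.71e-14). PLAU overlaps C10orf55 on the genome, and strand was not given for the counting, so reads of the pair may have been shared. MMP9, the gene of gelatinase B, fell from 147 ± 2.40 to 57.5 ± 5.01 FPKM (-1.33, edgeR adjusted p = 4.54e-11), and the neutrophil chemokine gene CXCL5 from 188 ± 19.0 to 44.2 ± 1.27 FPKM (-2.07, edgeR adjusted p = 8.54e-13). THBS1, which encodes the matrix glycoprotein thrombospondin, rose from 235 ± 11.9 to 493 ± 9.91 FPKM (1.09, edgeR adjusted p = 1.17e-12). C3, the central component of complement, rose from 7.26 ± 0.0141 to 46.2 ± 5.07 FPKM (2.70, edgeR adjusted p = 9.73e-13). All 5 kept their calls when any single library was left out.

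**Figure D2:**
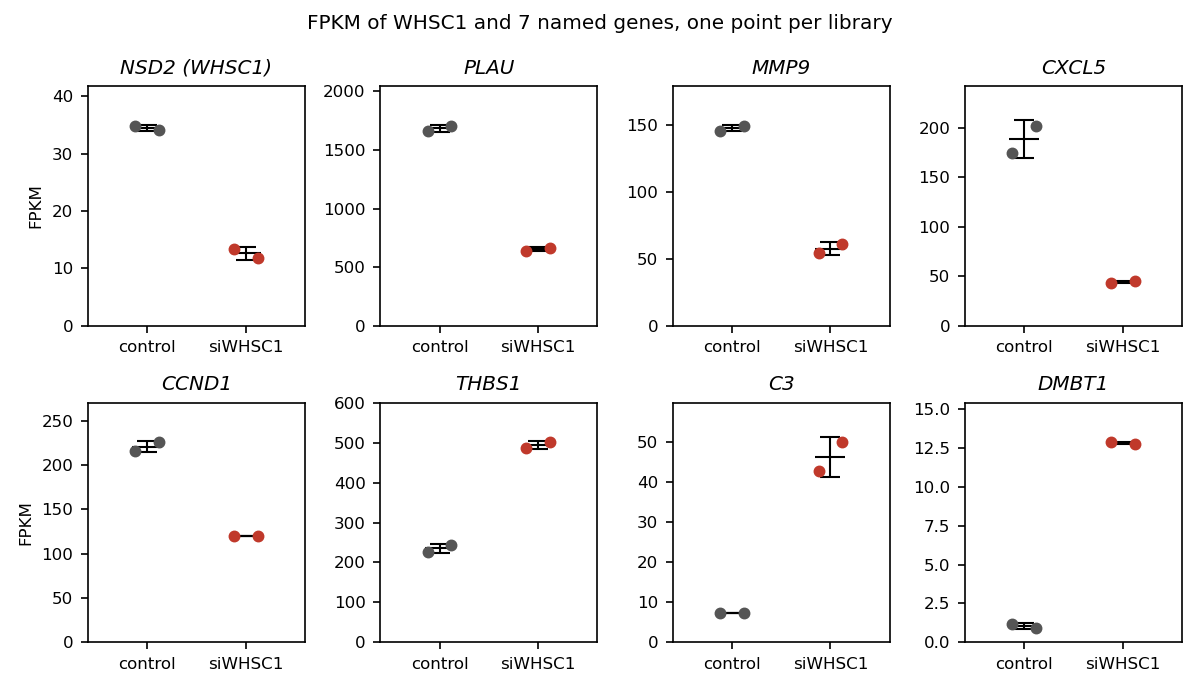
FPKM (vertical axis) of WHSC1 (NSD2) and 7 other named genes in the control and siWHSC1 libraries, with 1 point per library, a horizontal bar at the mean and whiskers of 1 SD (n = 2). WHSC1, PLAU, MMP9, CXCL5 and CCND1 were lower and THBS1, C3 and DMBT1 higher in both siWHSC1 libraries than in either control library.

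The largest rise among the named genes was that of ROS1, a receptor tyrosine kinase gene, which went from 0.28 ± 0.156 to 3.80 ± 0.283 FPKM (log2 fold change 3.75, SE 0.26, edgeR adjusted p = 1.27e-08). DMBT1, a gene of a secreted scavenger receptor protein of mucosal surfaces, rose from 1.06 ± 0.205 to 12.8 ± 0.0707 FPKM (3.61, SE 0.13, edgeR adjusted p = 1.62e-12). Other named rises were COL15A1 (2.85), the nucleotide receptor gene P2RY6 (2.83) and LTB, which encodes lymphotoxin beta (2.76). S100A8 (2.55), the serpin gene SERPINB3 (2.47) and the non-coding LINC01311 (2.46) rose too. None of these 6 overlapped another tested gene, but reads shared with similar copies were not checked for them. Their edgeR adjusted p ran from 1.04e-05 to 0.0160, and none of these 6 stayed past the test without control replicate 2. FAM86B1 (3.71), RABL2A (3.60) and CORO7-PAM16 (3.16) also ranked here, but reads are shared with near-identical copies or with the genes that the readthrough transcript spans, and their values are uncertain.

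On the side of the falls, IL23A, which encodes a subunit of interleukin 23, dropped from 59.5 ± 2.27 to 12.7 ± 2.91 FPKM (log2 fold change -2.20, SE 0.14, edgeR adjusted p = 4.03e-09). FAM43A fell from 24.2 ± 0.431 to 5.33 ± 0.156 FPKM (-2.16, SE 0.11, edgeR adjusted p = 2.54e-10). ESM1, the gene of an endothelial proteoglycan, fell from 3.52 ± 0.389 to 0.55 ± 0.283 FPKM (-2.70, edgeR adjusted p = 0.000115). The homeobox gene SIX3 (-2.56), the oxysterol hydroxylase gene CYP39A1 (-2.47) and the keratin gene KRT37 (-2.39) were lower at edgeR adjusted p values of 0.00570 to 0.00974. The keratin gene KRT83 (-2.53, edgeR adjusted p = 0.00707) had 2.25 and 13.84 FPKM in the control libraries, and without control replicate 2 its change was -0.70 (edgeR adjusted p = 0.247). TMX2-CTNND1, SENP3-EIF4A1 (-2.82), BIVM-ERCC5 (-2.73), CCDC74B (-3.36) and NPIPA5 (-3.08) share reads with overlapping genes or near-identical copies and are uncertain. TMX2-CTNND1 was at 0 in both siWHSC1 libraries, and the controls stood 70.1-fold above a floor of 3 counts over the group. That floor covers counting error and not how reads were divided between genes, so the ratio is no lower bound for the transcript. Summed with the genes it spans, the locus changed by a log2 fold change of only -0.14. Calls for ESM1, SIX3, CYP39A1 and KRT37 were lost without control replicate 1 or 2.

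Genes of glycolysis and the hypoxia response were the list with the lowest p. All 27 members were tested, 18 rose, 0 fell and 9 did not pass the test (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.23. CA9, a carbonic anhydrase gene induced by hypoxia, rose from 7.13 ± 2.05 to 24.0 ± 1.00 FPKM (1.78, edgeR adjusted p = 5.07e-07). The angiogenic factor gene VEGFA (0.49) and the phosphofructokinase genes PFKL (0.56) and PFKP (0.48) rose as well. The shift against all other genes gave an adjusted p of 5.15e-08 in camera with a preset correlation of 0.01. Of the 24 lists tested, 7 passed in this way and 0 passed with an estimated correlation, where the camera adjusted p was 0.401 for each of the 7. The estimated correlation ranged from -0.029 (mesenchymal genes) to 0.161 (integrin and focal adhesion genes) among these 7. For the interferon-stimulated genes it was -0.020, below the preset value, and the list still did not pass. The run has few residual degrees of freedom, so the 2 runs together leave the shifts of the lists open.

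Interferon-stimulated genes moved the other way. Of 27 tested members of 31, 0 rose, 13 fell and 14 did not pass (0 and 13 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 2.83e-05, adjusted p = 0.401 with an estimated correlation). IFI44 fell from 7.005 ± 0.785 to 2.36 ± 0.354 FPKM (-1.54, edgeR adjusted p = 0.000301), and the antiviral GTPase gene MX1 (-1.50) and IFIT3 (-0.88) fell too. The calls of IFI44 and IFIT3 were lost without control replicate 1 or 2, and that of MX1 without control replicate 2.

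Targets of the unfolded protein response and of the transcription factor ATF4 rose more often than they fell. Of 28 members, 14 rose, 3 fell and 11 did not pass (15 and 4 adjusted over the list alone, camera adjusted p = 0.000120, adjusted p = 0.401 with an estimated correlation). HYOU1, an endoplasmic reticulum chaperone gene, rose from 80.5 to 122 ± 1.48 FPKM (0.63, edgeR adjusted p = 6.63e-09). The calcium-binding chaperone gene CALR (0.48), the mTOR inhibitor gene DDIT4 (0.99) and the pseudokinase gene TRIB3 (0.86) also rose, and all 4 kept their calls without any 1 library. The 3 that fell were DNAJB9 (-0.59), VLDLR (-0.59) and EDEM1 (-0.25), named after their values were seen. Their edgeR adjusted p values of 0.0228 to 0.0489 were lost in DESeq2 and without either control library.

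Ribosomal protein genes and genes of DNA replication showed small rises. Of 32 ribosomal protein genes, 13 rose, 0 fell and 19 did not pass (13 and 0 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.000231, adjusted p = 0.401 with an estimated correlation). RPL11 (0.33), RPL13 (0.30) and RPL8 (0.23) were among the lowest p values. The 16 housekeeping genes, which did not pass camera, had a median of 0.08, and all tested genes had a median of -0.006. The housekeeping list holds the ribosomal protein gene RPLP0 (0.19), EEF1A1 (0.29) and the glycolysis genes PGK1 (0.23) and GAPDH (0.12). It is therefore no separate reference, and whether so small a rise was particular to ribosomal protein genes was left open. Of 32 DNA replication and G1/S genes, 11 rose, 1 fell and 20 did not pass (13 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.000364, adjusted p = 0.401 with an estimated correlation). RRM1, a subunit gene of ribonucleotide reductase, rose by 0.42, and the replicative helicase genes MCM3, MCM2 and MCM7 by 0.37, 0.36 and 0.24. UHRF1, a chromatin factor gene named after its value was seen, fell by 0.16 (edgeR adjusted p = 0.0345, not past in DESeq2). All 3 ribosomal and 4 replication examples lost their calls without control replicate 2.

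Cell adhesion genes shifted downwards. Of 24 integrin and focal adhesion genes, 3 rose, 12 fell and 9 did not pass (3 and 13 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.000383, adjusted p = 0.401 with an estimated correlation). The laminin chain gene LAMA3 fell from 512 to 305 ± 6.58 FPKM (-0.70, edgeR adjusted p = 9.16e-10). The collagen and laminin receptor genes ITGA2 (-0.52) and ITGA3 (-0.45) fell as well. The 3 that rose were ITGB8 (1.18), the shared integrin beta chain gene ITGB1 (0.28) and the focal adhesion kinase gene PTK2 (0.27), all named after their values were seen. None of these 3 stayed past the test without control replicate 2.

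The list of mesenchymal genes passed in the upward direction. Of 23 tested members of 26, 7 rose, 2 fell and 14 did not pass, in the list alone likewise 7 and 2 (counts adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00597, adjusted p = 0.401 with an estimated correlation). THBS1 (1.09), the lysyl oxidase gene LOXL2 (0.83), the collagen gene COL1A1 (0.76) and the tenascin gene TNC (0.59) rose. Among the 14 that did not pass were VIM (0.11), CDH2 (0.10), SNAI1 (0.11), SNAI2 (-0.02) and TWIST1 (-0.02), named after their values were seen. The 2 that fell, named after their values were seen, were ZEB1, a transcriptional repressor of CDH1 (-1.12, SE 0.34, from 0.975 to 0.45 FPKM, edgeR adjusted p = 0.0221), and TGFBI (-0.17). The list's camera adjusted p was 0.0519 without control replicate 1 and 0.0562 without control replicate 2, and the call of ZEB1 was lost when any single library was left out.

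**Figure D3:**
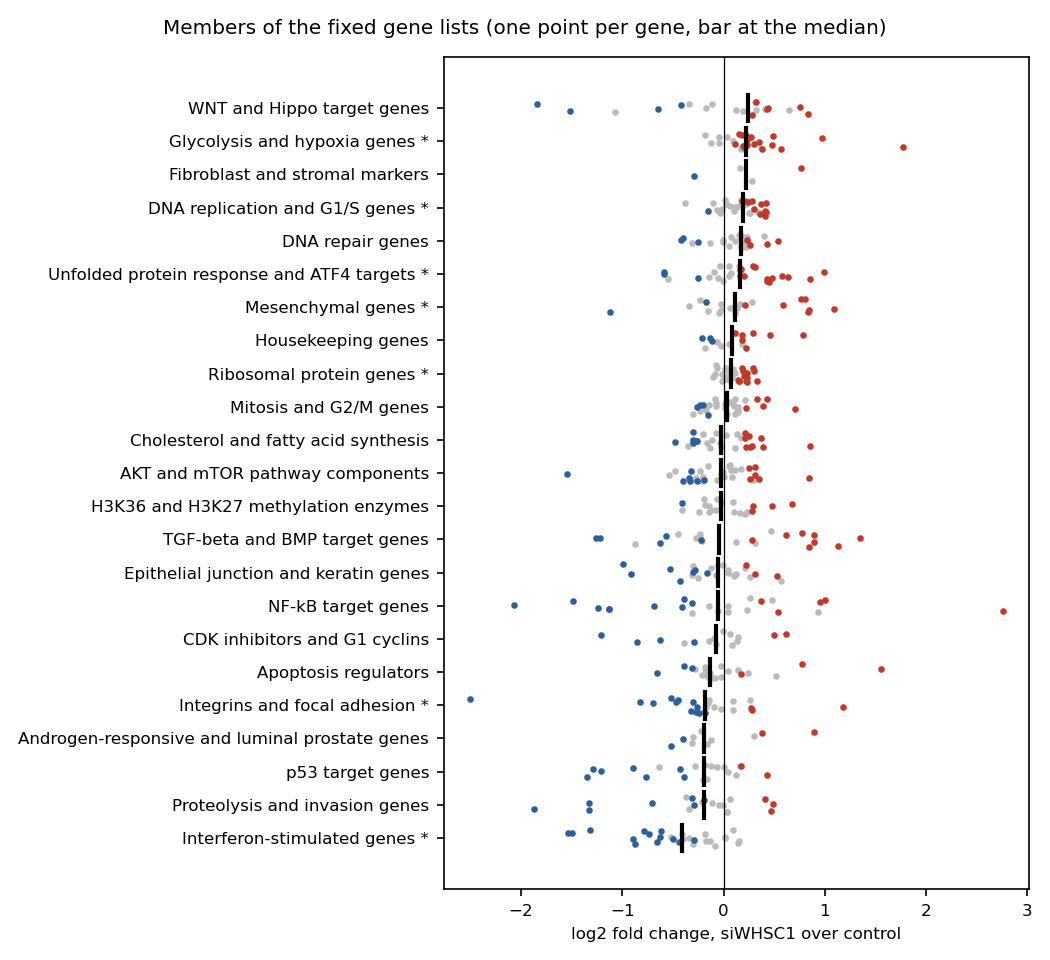
Log2 fold change (siWHSC1 over control, horizontal axis) of every tested member of the gene lists reported here that had at least 3 tested members, 1 point per gene and a black bar at each list's median. Red and blue points rose and fell at an edgeR adjusted p under 0.05, grey points did not pass, and the 7 lists marked with an asterisk passed camera with the preset correlation, the interferon-stimulated genes having the lowest median (-0.41).

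Epithelial junction and keratin genes did not pass as a list, although single members changed strongly. Of 25 tested, 3 rose, 7 fell and 15 did not pass (5 and 9 adjusted over the list alone, camera adjusted p = 0.125). CLDN4, a tight junction claudin gene, fell from 359 to 177 ± 2.22 FPKM (-0.99, edgeR adjusted p = 2.45e-11), and the keratin genes KRT19 (-0.92) and KRT7 (-0.53) fell too. CDH1, the gene of E-cadherin, rose by 0.31 (edgeR adjusted p = 2.85e-05, lost without control replicate 2). Proteolysis and invasion genes likewise did not pass as a list (camera adjusted p = 0.0642), with 3 risen, 7 fallen and 9 not past among 19 tested (3 and 8 adjusted over the list alone). Beside PLAU and MMP9, the collagenase gene MMP1 fell by 1.87 on the log2 scale (edgeR adjusted p = 0.000662) and the metalloproteinase inhibitor gene TIMP1 by 0.70, both named after their values were seen, whereas MMP14 (0.47) and the hyaluronan receptor gene CD44 (0.41) rose. This list was past the test in camera without siWHSC1 replicate 2 (adjusted p = 0.0419) and with a correction for GC content added after seeing the data (adjusted p = 0.0445).

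The lists of CDK inhibitors and G1 cyclins and of mitosis genes did not pass camera, although single members changed. CCND1, the cyclin D1 gene, fell from 221 ± 6.51 to 120 ± 0.141 FPKM (-0.86, edgeR adjusted p = 6.66e-11), and CDKN1A, which encodes the CDK inhibitor p21, from 81.1 ± 3.99 to 34.4 ± 0.983 FPKM (-1.21, edgeR adjusted p = 1.06e-09). CDK6 (0.62) and RBL1 (0.49) rose. Of the 15 tested CDK inhibitor and G1 cyclin genes, 2 rose, 4 fell and 9 did not pass (2 and 5 adjusted over the list alone, camera adjusted p = 0.291). Of 20 p53 targets, 2 rose, 7 fell and 11 did not pass (2 and 7 adjusted over the list alone, camera adjusted p = 0.0642, 0.0352 without siWHSC1 replicate 1 and 0.0431 with the GC correction). CDKN1A, TP53INP1 (-0.90), ZMAT3 (-0.77) and PHLDA3 (-0.43) were among those that fell, and the repair gene XPC, named after its value was seen, rose by 0.43. PC-3 cells are known to lack functional p53. Of 32 mitosis genes, 5 rose, 4 fell and 23 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.360), with BIRC5, the survivin gene, higher by 0.71 and AURKB by 0.43, and FOXM1 (-0.20) and KIF11 (-0.23), named after their values were seen, lower. The calls of FOXM1 and KIF11 were lost in DESeq2 and without control replicate 1 or 2. Of 26 DNA repair genes, 4 rose, 3 fell and 19 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.125), with XRCC2 at 0.54 and PARP1 at -0.42. Of 22 apoptosis regulators, 3 rose, 3 fell and 16 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.583). BID, a pro-apoptotic gene, rose by 0.78 (lost without control replicate 1 or 2), and MCL1, an anti-apoptotic gene, fell by 0.39. This list's median was -0.13 and its mean 0.02.

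NF-kB targets split in both directions. Of 23 tested, 5 rose, 9 fell and 9 did not pass (5 and 10 adjusted over the list alone, camera adjusted p = 0.291). The neutrophil chemokine genes CXCL5 (-2.07), CXCL3 (-1.49) and CXCL2 (-1.14) fell, as did TNFAIP3 (-0.68), a feedback inhibitor of NF-kB, whereas SOD2 (0.95), PTX3 (1.00), LTB (2.76), IL6 (0.54) and CXCL1 (0.37) rose. CXCL2, TNFAIP3, IL6 and CXCL1 were named after their values were seen. The calls of LTB, IL6 and CXCL1 were lost without control replicate 1 or 2. Of 22 TGF-beta and BMP targets, 8 rose, 5 fell and 9 did not pass (8 and 8 adjusted over the list alone, camera adjusted p = 0.275, direction up), with a median of -0.04 and a mean of 0.07. LTBP2 (1.13), PMEPA1 (0.90), the activin subunit gene INHBA (0.77) and TGFB2 (0.61) rose, whereas ID2 (-1.26), BAMBI (-1.22), SMAD3 (-0.63) and FST (-0.57), named after their values were seen, fell. The calls of ID2 and BAMBI were lost without control replicate 1 or 2. Of 20 WNT and Hippo targets, 6 rose, 4 fell and 10 did not pass (8 and 5 adjusted over the list alone, camera adjusted p = 0.291, direction up), with a median of 0.24 and a mean of -0.05. CCN1 rose by 0.76 and MYC by 0.28. The 4 that fell were LEF1 (-1.84, edgeR adjusted p = 0.00288), SP5 (-1.52, edgeR adjusted p = 0.00490), CRIM1 (-0.65) and the WNT antagonist gene DKK1 (-0.42). AXIN2 (-1.07, edgeR adjusted p = 0.146) did not pass. LEF1, SP5, AXIN2 and MYC were named after their values were seen and not followed in the other settings. The list pools targets of both pathways, so its direction need not hold for the WNT targets alone.

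Components of the AKT and mTOR pathway did not pass as a list. Of 31 tested, 6 rose, 7 fell and 18 did not pass (7 and 8 adjusted over the list alone, camera adjusted p = 0.749). SGK1, a kinase gene related to AKT, fell from 7.69 to 2.59 ± 0.453 FPKM (-1.54, edgeR adjusted p = 3.49e-05), and the insulin receptor substrate gene IRS2 rose by 0.84. AKT1 rose by 0.25. RICTOR, which encodes the defining subunit of mTOR complex 2 and was named after its value was seen, fell from 7.62 ± 0.615 to 5.92 ± 0.141 FPKM (-0.33, SE 0.09, edgeR adjusted p = 0.00973). Its call was lost in DESeq2 (adjusted p = 0.177) and when any single library was left out (adjusted p from 0.0715 to 0.168). Other subunit genes of mTOR complex 2 did not fall with it. MLST8 (0.31, edgeR adjusted p = 0.00930) and MAPKAP1 (0.26, edgeR adjusted p = 0.0164) rose. MTOR (-0.15, edgeR adjusted p = 0.106) and PRR5 (0.30, edgeR adjusted p = 0.206) did not pass. These genes were named after their values were seen and not followed in the other settings. Of 21 other methylation enzymes of H3K36 and H3K27, 4 rose, 1 fell and 16 did not pass (4 and 2 adjusted over the list alone, camera adjusted p = 0.595). The demethylase genes KDM2B (0.68), KDM2A (0.48) and KDM4B (0.28) and the Polycomb partner gene JARID2 (0.29) were the risen members. KDM4C (-0.41, edgeR adjusted p = 0.0410), named after its value was seen, fell, and its call was lost when any single library was left out.

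Lists of lipid synthesis, prostate and reference genes did not pass camera. Of 27 cholesterol and fatty acid synthesis genes, 9 rose, 6 fell and 12 did not pass (11 and 6 adjusted over the list alone, camera adjusted p = 0.360, direction up), with a median of -0.02 and a mean of 0.02. INSIG1 (0.85), DHCR7 (0.39) and FASN (0.22) rose, whereas MSMO1 (-0.48) and SQLE (-0.30), named after their values were seen, fell, though not past the test without control replicate 1 or 2. Of 10 tested androgen-responsive and luminal prostate genes, 2 rose, 2 fell and 6 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.758), with PMEPA1 (0.90) and FKBP5 (0.38) up and ELL2 (-0.52) and HOXB13 (-0.40) down. Of 16 housekeeping genes, 7 rose, 3 fell and 6 did not pass (7 and 3 adjusted over the list alone, camera adjusted p = 0.0917, past the test in fry at an adjusted p of 0.0171), with the transferrin receptor gene TFRC higher by 0.78 and EEF1A1 by 0.29. POLR2A (-0.21), named after its value was seen, fell, but not past the test without control replicate 1 or 2. Markers of other cell types were scarce. Of the 14 fibroblast markers 4 were tested, of which COL1A1 rose, FBLN1 (-0.29) fell at an edgeR adjusted p of 0.0499, and COL3A1 (0.28) and COL1A2 (0.16) did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.291). Of 14 blood cell markers 2 were tested, CD68 (0.27, edgeR adjusted p = 0.0865) and LYZ (-0.07, edgeR adjusted p = 0.794), and of 15 neuroendocrine markers ENO2 (0.23) rose and SNAP25 (0.48, edgeR adjusted p = 0.470) did not pass. The 13 mitochondrially encoded genes were not among the tested genes.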

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

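The GC correction and the summing of readthrough genes and copies were chosen after the results were seen, and all other alternatives were planned. WHSC1 was called in every setting, at log2 fold changes of -1.33 to -1.49. The count of 3510 called genes (1791 higher, 1719 lower) stayed within 1.5 times with RLE size factors (3477), library size only (3593), at least 50 counts (3563), the robust fit (3725), the legacy fit (3478), the GC correction (3649), summed loci (3594) and limma on log2(FPKM + 1) (2356, although only 1145 higher). It fell to 1417 (822 higher, 595 lower) in DESeq2, all of them among the 3510, and to 1208 (691 and 517) without a filter, where 19710 genes were tested and 4993 had an unadjusted p under 0.05. Limma gave 2313 (1132 higher) on log2(FPKM + 0.1) and 1459 (763 and 696) on log2(FPKM + 1) without a filter. The cause was not tested for these tools and filters. By construction, the stricter thresholds left fewer, 349 (129 and 220) at 2-fold or more and 2123 (1138 and 985) at an adjusted p under 0.01. With 1 library fewer the counts ran from 284 without control replicate 2 to 2219 without siWHSC1 replicate 1, those higher from 167 to 1230 and those lower from 117 to 989. Why leaving out a control cost more calls was not tested. With library size only, 45.1% of the calls were higher, against 51.0%.

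Of the 158 singly picked genes past the threshold, some of them not reported here, 142 were tested in every setting. Of these, 101 kept their calls under every alternative with all libraries, and 62 also when each library was left out. Without control replicate 1, 87 of 157 tested kept their calls, and in DESeq2 118 of 147. The calls kept were 62 without control replicate 2, and 139 and 131 without siWHSC1 replicate 1 or 2. Over these genes and alternatives, 379 values lost the call and 1 changed sign, SENP3-EIF4A1, at 0.42 once summed with the genes it spans (edgeR adjusted p = 5.19e-08). In that setting the value of a readthrough gene or copy is that of its whole locus, so a call kept there is not a call on the gene itself. LYZ, not past the threshold, ran from -0.31 to 0.14 as libraries were left out. In the simulation 27.1% of the smallest changes were recovered. It gave 143 calls among 13811 genes, against 3510 among 14011 in the data. With a smaller share of calls, the same adjusted p asks for a lower unadjusted p. The simulated share is therefore not the recovery in the data. How far depth and 2 libraries per group limited small changes there was not measured.

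Of 24 lists, 7 passed, 0 with an estimated correlation, 13 with fry, which does not compare a list with other genes, and 6 to 9 in the other settings. Fry added the lists of H3K36 and H3K27 enzymes (adjusted p = 0.0200), CDK inhibitors (0.0465), TGF-beta targets (0.0200), p53 targets (0.0367), fibroblast markers (0.0171) and housekeeping genes (0.0171). The androgen list changed direction in fry (adjusted p = 0.493) and without siWHSC1 replicate 2, its adjusted p running from 0.528 to 0.986 as libraries were left out, and the fibroblast list without a filter (adjusted p = 0.698). These lists were not past the threshold in camera, and the cause was not tested.

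With the replicate number as a block, 3510 genes were called (1790 higher, 1720 lower), 3431 of them shared. Among these genes only VLDLR lost its call (edgeR adjusted p = 0.0513), and the proteolysis list gained one (camera adjusted p = 0.0485). Deviations of same-numbered libraries correlated at 0.0469 across genes, and with 2 pairs whose numbers no label ties together they were not taken as paired.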

Other observations

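The tests of how closely the siWHSC1 libraries match were chosen after the result was seen, as were the check of how far 1 gene alone would move a sum and the genes named here outside the fixed rule. Annotation terms gave a further grouping of the genes, which overlaps the fixed lists, since translational elongation holds ribosomal protein genes. Of 1549 GO and KEGG terms, 31 passed camera with the preset correlation (24 up, 7 down) and 0 with an estimated correlation (smallest adjusted p = 0.921), and terms share members. Genes of translational elongation rose, 41 of 109 against 2 that fell (limma camera adjusted p = 5.70e-05). EEF1A2, the tissue-restricted elongation factor gene, rose from 44.7 to 125 FPKM (1.51, edgeR adjusted p = 2.53e-11), whereas RPS28, which has processed copies and overlaps another gene, was lower by a log2 change of -0.84. Of the mitochondrial terms the nucleoid passed, with 19 of 43 genes risen (2 fell, limma camera adjusted p = 0.000232), with the protease gene LONP1 at 0.80, as did the respiratory chain, with 17 of 50 (2 fell, limma camera adjusted p = 0.0342), with the cytochrome c gene CYCS at 0.68. The broader terms did not, with 57 risen and 23 fallen of 250 genes of the inner membrane (limma camera adjusted p = 0.101) and 44 and 15 of 200 of the matrix (limma camera adjusted p = 0.129), nor did the large ribosomal subunit (limma camera adjusted p = 0.0528). In the lumen of the endoplasmic reticulum 44 of 122 genes rose and 8 fell (limma camera adjusted p = 0.000779). COL6A3, a collagen gene, rose from 10.8 to 36.3 FPKM (1.78, edgeR adjusted p = 6.88e-13), and GANAB, a glucosidase gene of glycoprotein folding, by 1.42 (edgeR adjusted p = 8.54e-13). Genes annotated with protein disulfide isomerase activity rose in 9 of 19 cases and 0 fell (limma camera adjusted p = 0.00108). P4HB (0.41) and the oxidase gene ERO1A (0.66) were among them. Collagen fibril genes rose in 15 of 31 cases (1 fell, limma camera adjusted p = 0.0121).

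The terms that went down included genes of epithelial differentiation and of neuronal growth cones. Of 34 keratinocyte differentiation genes 11 fell and 1 rose (limma camera adjusted p = 0.0191), among them the receptor kinase gene EPHA2 (-0.39) and TMX2-CTNND1, whose reads are shared. Of 78 growth cone genes 20 fell and 6 rose (limma camera adjusted p = 0.0314). Among single genes with very low p outside the lists, FAM20C, a kinase gene for secreted proteins, rose from 27.4 to 118 ± 4.94 FPKM (2.13, edgeR adjusted p = 3.33e-13), and the lipocalin gene LCN2 from 360 to 885 FPKM (1.33, edgeR adjusted p = 3.18e-12). FTH1, the ferritin heavy chain gene, fell from 3002 to 1423 FPKM (-1.05, edgeR adjusted p = 3.49e-13), but it has processed copies and overlaps another gene, so its value is uncertain. The genes named here and in the paragraph before, TMX2-CTNND1 apart, kept their calls in every setting that tested them. Isoform use, read from the deposited gene length, showed no call in limma (0 of 5329 genes, 326 at an unadjusted p under 0.05 against 266 by chance, smallest adjusted p = 0.151), and no other tool was run. A log2 length ratio of 0.26 at a single gene did not pass (limma adjusted p = 0.434), so shifts of this size can have been missed.

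The siWHSC1 libraries lay somewhat closer to each other than the control libraries did, with a ratio of chi-square per gene, siWHSC1 pair over control pair, of 0.903. Their chi-square per gene of 1.38 (95% bootstrap interval 1.34 to 1.42) argues against 1 library deposited under both labels. Whether both carry the same siRNA cannot be told apart from different siRNAs with like effects, since 8 genes differed between them against 39 between the controls (binomial test, adjusted) and no siRNA sequence was given. An effect of WHSC1 depletion shared by both libraries remains a hypothesis beside an off-target effect of a common siRNA.

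Several of the largest fold changes lay at readthrough genes and near-identical copies. Of 58 tested readthrough genes 15 were called, with a median size of log2 change of 1.61, and the sums with the genes they span changed by a median of 0.262. The readthrough gene alone would have moved these sums by a median of only 0.191. Over the set, reads divided differently therefore cannot be told apart from a real change of the readthrough transcript. Single loci differed. The sums of CORO7-PAM16 (0.02 against 0.31 if it alone had changed) and BIVM-ERCC5 (-0.01 against -0.40) barely moved, as divided reads would give. Those of P2RX5-TAX1BP3 (0.40 against 0.40) and PHOSPHO2-KLHL23 (-0.41 against -0.46) moved about as far as the gene alone would have moved them. In 5 families of copies the sums changed by a median of 0.281, against 0.51 if the largest-changing member alone had changed, which is consistent with divided reads in PLGLB (0.01 against 1.01) and NPIPA (-0.54 against -1.92). The sum of CCDC74 moved further than that (-1.93 against -0.51), and RABL2 (0.21 against 0.31) and FAM86 (0.28 against 0.06) leave both open, as does the design for a biological change of any copy.

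The interferon-stimulated genes had a median log2 fold change of -0.41, and -0.42 after the GC correction, which argues against a GC trend as the cause. A response to the control siRNA that raised these genes in the controls cannot be told apart from a fall after WHSC1 depletion. The only interferon gene counted was IFNE, with 16 counts in the controls (6 and 10) and 10 and 5 in the siWHSC1 libraries. No other interferon gene looked for, IFNB1 and the IFNA and IFNL genes among them, was listed in any library. These counts do not decide the question, and no untransfected cells were analysed here. A lower interferon tone after WHSC1 depletion is therefore a hypothesis.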
